A study of Homo sapiens with 477 samples.

How the data were processed

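ATAC-seq was performed on human liver, per the labels' protocols from frozen tissue pieces of 50 mg with the omni-ATAC procedure on 50000 nuclei, sequenced as paired 150-bp reads. The labels describe 477 sequencing runs of 398 libraries and 138 tissue sample identifiers, and the series' design text gives 138 donors; 79 libraries were sequenced more than once. All runs fell into 1 group, so no comparison between groups of samples was possible. The authors deposited 1 consensus list of peaks for the whole series, which gives a chromosome, a start, a stop and an identifier for each peak, in base pairs of build GRCh38. By its deposited description the list has refined boundaries, includes secondary peaks, and was limited to peaks with a maximum coverage of at least 7 and a width of at least 200 bp; how coverage was pooled over donors is not given in the sources used here. The submitters' processing notes name cutadapt, Bowtie2, SAMtools, Picard, bedtools and MACS2 without versions or roles. How reads were shifted for the transposase, how reads with several matches were treated and how donors entered the consensus are not given in the sources used here. A site open in few donors, or in a rare cell type, can fall under the coverage minimum, and a region where reads match several places can lose its peaks.

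Peaks on the autosomes and the X chromosome were used, and 376 peaks on the Y chromosome were left out. No peaks overlapped each other, and 2298 neighbouring pairs touched. Gene positions came from the RefSeq gene table of assembly GRCh38.p14, which gives start, end and class but no strand and no exons. Of 578 symbols in the lists 577 matched a protein-coding gene. Coordinates are given counted from 1.

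Several tests departed from the design set before the data were examined, because no genome sequence or strand was used here. Both annotated ends of a gene took the place of its start. Gene bodies of protein-coding and other genes took the place of exons and introns. The sequence considered ran from the first to the last peak of a chromosome, without the 39 stretches over 500 kb (121 Mb in all) that held no peak. Genes were matched on quintiles of gene length and of local protein-coding gene number in place of CpG content. The tests of 30 sequence motifs, of repeat content and of CpG classes were not run, nor were the alternatives of any transcript start and of leaving out secondary peaks, which the identifiers do not mark.

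A gene end was called accessible where a peak overlapped the 1000 bp either side of it by at least 1 bp. Distal peaks of a gene were those with a midpoint within 50 kb of an end and more than 1 kb from every protein-coding gene end, averaged over the gene's 2 ends; they made up 93.0% of all peaks. Peaks were placed in the annotation by their midpoint, in the order gene end, protein-coding body, other body, intergenic. Intervals at 95% came from a jackknife over 5 Mb blocks for location and for differences between protein-coding genes and long non-coding RNA genes or pseudogenes, from 1000 bootstrap draws of such blocks for width, from 10000 bootstrap draws of genes for folds and for differences between classes of gene lists, which do not allow for neighbouring genes sharing peaks, and from Wilson's method for shares of genes. Background shares at gene ends used 20 random shifts of 500 to 1000 kb.

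The 23 gene lists and their 4 classes were set before the data were examined: 10 hepatocyte lists (246 genes), 5 lists of other liver cells (115 genes), 6 of other tissues (162 genes) and 2 of housekeeping genes (54 genes; cholesterol synthesis and ribosomal proteins). The mean of a list was compared with 100000 random lists of protein-coding genes drawn with replacement within the matching strata, two-sided, and p-values were adjusted by Benjamini-Hochberg over the 23 lists and separately over the 4 classes, at 0.05. Differences between classes used 100000 permutations of the class labels within strata. Neighbouring genes share peaks, so genes are not fully independent and these p-values are too small to that extent. The genes named were, over the genome, the 20 protein-coding genes with the most distal peaks, skipping a gene whose start lay within 100 kb of one already taken, and, per list, the 3 members with the most distal peaks and the first 3 without an accessible end; some genes that meet this rule are not reported here. ALB, HNF4A and CTRC, the genes with near-identical copies and those of the richest 100 kb windows were chosen outside this rule after the data had been seen.

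The list test was checked on simulated data over the same 19974 genes. Simulated lists were drawn at random from all genes, so the check does not cover lists with neighbouring members that share peaks. At no true effect, 7 of 100 simulated lists of 25 genes and 6 of 100 lists of 150 genes had p under 0.05. At a true fold of 1.25 these numbers were 66 and 100 of 100, and at a fold of 1.5 they were 92 and 100.

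Alternatives set in advance were peaks of at least 300 bp, merging of peaks closer than 50 bp, gene ends within 500 or 2500 bp, placement by any overlap, an overlap of at least 100 bp, windows of 25 and 100 kb, 1 gene per 250 kb, no matching, autosomes alone, bases in place of peak number, and long non-coding RNA genes added to gene density. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.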

Results

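The series profiled open chromatin in human liver by ATAC-seq, an assay in which the Tn5 transposase inserts sequencing adapters into accessible DNA. It holds 477 sequencing runs of libraries from 138 donors, with 1 to 5 libraries per tissue sample and 1 group, liver. The values analysed were 358304 consensus peaks, the intervals at which the authors called accessible chromatin over the series as a whole. The peaks carried coordinates in genome build GRCh38 but no height, coverage or value per donor, so the depth behind each peak is unknown, no donor could be compared with another, and no error between replicates could be had. Errors below are over genes or over stretches of the genome. The title of the series concerns genetic effects on accessibility; donor genotypes were not analysed here.

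Accessible sites were spread over 22 autosomes and the X chromosome, with 357928 peaks at 126.2 peaks per Mb. Chromosomes 22 and 19 were the densest, with 6994 peaks in 36.6 Mb and 9541 peaks in 55.4 Mb. The X chromosome held 55.1 peaks per Mb, below chromosome 4, the least dense autosome, at 106.5. The number of X copies per donor was not taken into account, and the list required a maximum coverage of at least 7. The median peak was 330 bp wide (range 200 to 3200 bp), and the peaks together covered 146.3 Mb, or 5.16% of the 2837 Mb considered. Chromosomes with more protein-coding genes per Mb had more peaks per Mb (Pearson's r = 0.619, permutation p = 0.0105; Spearman's rho = 0.757, permutation p = 0.0001; 23 chromosomes, two-sided). Without chromosomes 17 and 19, those farthest from the median gene density, r was 0.608 (permutation p = 0.00328). Over the 22 autosomes alone r was 0.745 (permutation p = 0.00093).

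**Figure D1:**
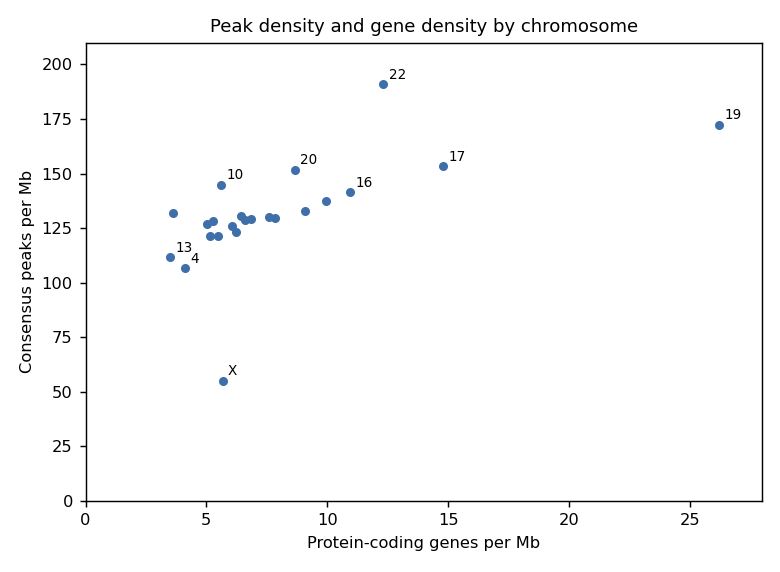
Consensus ATAC-seq peaks per Mb (y axis) against protein-coding genes per Mb (x axis), 1 point for each of 23 chromosomes, with the numbers of the densest and sparsest chromosomes printed beside their points. The X chromosome lies lowest at 55.1 peaks per Mb, and chromosome 22, with 6994 peaks in 36.6 Mb, lies highest.

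The ends of protein-coding genes were the most enriched part of the annotation. Peak midpoints within 1 kb of an annotated end of a protein-coding gene made up 24988 peaks, or 6.98% of all peaks in 2.55% of the sequence, 2.74 times the share under uniform placement (95% interval 2.67 to 2.82). The bodies of protein-coding genes held 48.7% of the peaks, a 1.14-fold enrichment (1.12 to 1.15). Bodies of other genes (0.870-fold, 0.849 to 0.893) and intergenic sequence (0.792-fold, 0.779 to 0.806) held fewer peaks than their length would give. Intervals came from a jackknife over 5 Mb blocks. The gene table gave no strand, so a gene's start and its far end were treated alike and promoters were not separated from the ends of transcription.

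Gene-end peaks were also the wide ones. Their median width was 568 bp against 325 bp for all other peaks, 1.75 times as wide (95% interval 1.70 to 1.81, block bootstrap). Of the gene-end peaks 30.7% were wider than 1000 bp, compared with 1.67% of peaks in protein-coding gene bodies and 1.35% of intergenic peaks. Gene ends thus held 59.2% of the 12964 peaks wider than 1000 bp. At ALB, which encodes serum albumin, the widest peak at a gene end lay at the upper end by coordinate. It spanned 1568 bp on chromosome 4 from 73421578 to 73423145. At HNF4A, a nuclear receptor of the hepatocyte lineage, the widest such peak lay at the lower end. That peak spanned 1240 bp on chromosome 20 from 44355210 to 44356449. Without strand, neither peak was assigned to a gene's start or far end. Width follows the authors' setting of peak boundaries and is not a measure of signal.

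**Figure D2:**
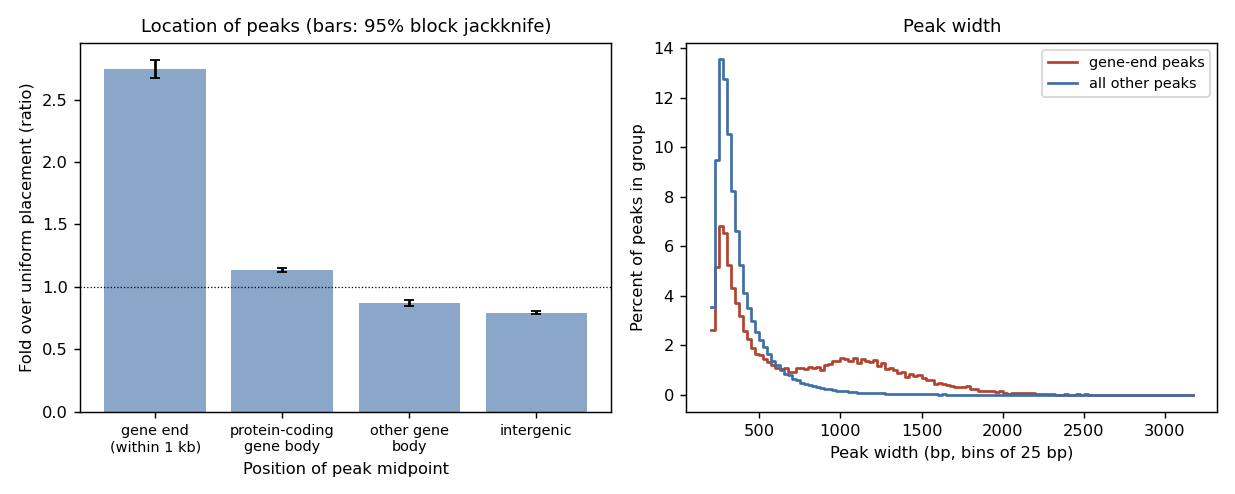
Left, fold of peak midpoints over uniform placement (ratio, y axis) in 4 parts of the annotation, with bars for the 95% block jackknife interval and a dotted line at 1; gene ends stand highest at 2.74. Right, percent of peaks (y axis) by peak width in bp (x axis, bins of 25 bp) for gene-end peaks and all other peaks, with medians of 568 and 325 bp.

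Most protein-coding genes had an accessible end, and pseudogenes mostly did not. A peak overlapped the 1 kb either side of at least 1 end in 17502 of 19974 protein-coding genes (87.6%, Wilson 95% interval 87.2 to 88.1), and both ends were accessible in 34.8% of them. Long non-coding RNA genes reached 64.2% (63.5 to 64.9) and pseudogenes 33.6% (32.9 to 34.3). Among the small RNA genes, 280 tRNA genes (65.3% of them, 60.7 to 69.6), 45% of 1911 microRNA genes (42.8 to 47.2) and 24.7% of 1196 small nucleolar RNA genes (22.4 to 27.3) had an accessible end. Intervals of the same genes shifted by 500 to 1000 kb met a peak in 47.8% of cases for protein-coding genes, 43.8% for long non-coding RNA genes, 32.1% for pseudogenes, 27.6% for tRNA genes, 29.8% for microRNA genes and 29.1% for small nucleolar RNA genes. Small nucleolar RNA genes thus lay below their shifted share, and pseudogenes lay close to theirs. Protein-coding genes exceeded long non-coding RNA genes by 23.4 percentage points (95% interval 21.9 to 25.02, block jackknife) and pseudogenes by 54.01 points (52.5 to 55.5). These are differences of raw shares, from which the unequal shifted shares were not subtracted. The shifted share differed between classes for reasons that were not tested, and it is the background for each class.

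Genes of hepatocyte function stood among the most peak-rich in the genome. Around the genes of the 10 hepatocyte lists, which have 20 to 34 members each, the mean number of distal peaks, those within 50 kb of a gene end and more than 1 kb from every protein-coding gene end, was 22.5 compared with 14.1 around matched protein-coding genes, a 1.59-fold excess (95% interval 1.53 to 1.66, adjusted p = 4e-05). Of these genes 220 (89.4%) lay above the genome median of 13.5, and 43.1% lay above the 90th percentile. Genes of the other liver cells showed a smaller excess (1.16-fold, 1.08 to 1.249, adjusted p = 0.00257), as did housekeeping genes (54 genes, 1.23-fold, 1.09 to 1.37, adjusted p = 0.00257). Genes of other tissues did not differ detectably from their matched genes (162 genes, 0.959-fold, 0.884 to 1.03, adjusted p = 0.332). Hepatocyte genes had 9.08 more distal peaks than genes of other tissues (95% interval 7.67 to 10.4, bootstrap over genes) and 6.39 more than genes of the other liver cells (4.91 to 7.87), each with adjusted p = 1e-05 when class labels were permuted. Folds were tested against 100000 random lists matched on gene length and local gene number, two-sided, with Benjamini-Hochberg adjustment over 4 classes and over 23 lists; the smallest unadjusted p such a test can give is 1e-05.

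All 10 hepatocyte lists had more distal peaks than matched genes, from 1.40-fold for glucose and glycogen metabolism (adjusted p = 0.000736) to 1.82-fold for hepatocyte transcription factors (1.60 to 2.05). All 22 transcription factor genes lay above the genome median; RXRA, the shared partner of many nuclear receptors, had 44 distal peaks, CEBPA, a regulator of hepatocyte differentiation, 35.5, and CREB3L3 31.5. Complement and acute phase genes followed at 1.76-fold (1.59 to 1.94), with 30 of 31 above the median and C8B (39.5), C3 (37) and ORM1 (36) at the head. The 20 plasma carrier genes stood at 1.74-fold (1.53 to 1.92) with 18 above the median, led by SERPINA1 (35), which encodes alpha-1 antitrypsin, AFM (29) and AZGP1 (29). Xenobiotic metabolism stood at 1.64-fold (1.499 to 1.78) with 32 of 34 above the median, led by the epoxide hydrolase gene EPHX1 (35), the alcohol dehydrogenase gene ADH1B (32) and CYP2E1 (31.5).

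Apolipoprotein and lipoprotein genes had a 1.62-fold excess (1.41 to 1.85) with 25 of 27 above the median, among them APOB (39), which encodes the main structural protein of liver-secreted lipoproteins, and SCARB1 (35.5). Coagulation factor genes stood at 1.52-fold (1.30 to 1.73), 18 of 23 above the median, and their highest members F7 (35.5), CPB2 (33) and F10 (31) all lie on chromosome 13. Bile acid genes stood at 1.47-fold (1.28 to 1.68) with 19 of 20 above the median, headed by BAAT (36), which conjugates bile acids, and the transporter genes ABCB4 and ABCC3 (28 each). Fatty acid and ketogenesis genes stood at 1.46-fold (1.22 to 1.71) with 17 of 21 above the median, including ACSL1 (39.5) and GPAM (30.5). Urea cycle and amino acid genes stood at 1.45-fold (1.26 to 1.63) with 21 of 26 above the median, including AGXT (31.5), the urea cycle genes CPS1 (29) and ASS1 (28). Of the 22 glucose and glycogen genes 18 lay above the median, among them G6PC1 (30.5) and IRS2 (30.5). Adjusted p over the 10 lists ran from 3.83e-05 to 0.000736. F7 and F10 lie within 100 kb of each other on chromosome 13, so their windows share peaks.

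Among lists of the other liver cells, macrophage and Kupffer cell genes (1.30-fold, 1.11 to 1.48, adjusted p = 0.0209) and endothelial genes (1.27-fold, 1.10 to 1.48, adjusted p = 0.0232) had an excess of distal peaks. SLC40A1 (27.5), the iron exporter ferroportin, HMOX1 (27), which breaks down haem, and MARCO (25.5) led the former, and EGFL7 (37), FCN2 (31.5) and CDH5 (26.5) the latter. No difference passed the test for cholangiocyte genes (1.13-fold, adjusted p = 0.402; KRT7 26.5, AQP1 26, TFF3 25.5), stellate cell and fibroblast genes (1.10-fold, adjusted p = 0.543; COLEC11 28, PDGFRB 26.5, DES 23.5) or lymphocyte genes (1.03-fold, adjusted p = 0.862; GNLY 28.5, IKZF1 24.5, CD5 22). Cholesterol synthesis genes had an excess (1.32-fold, 1.06 to 1.60, adjusted p = 0.0201), among them INSIG1 (34.5) and LSS (32). Ribosomal protein genes missed the threshold (1.18-fold, 1.02 to 1.34, adjusted p = 0.0820; RPS3 31, RPL3 27, RPL13 25). The macrophage call was lost with peaks of at least 300 bp (1.21-fold, adjusted p = 0.173), with 100 kb windows (1.18-fold, adjusted p = 0.153) and with covered bases in place of peak number (1.24-fold, adjusted p = 0.0838). The cholesterol synthesis call was lost with 100 kb windows (1.23-fold, adjusted p = 0.0632).

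None of the 6 lists of other tissues differed detectably from matched genes in distal peaks. Folds were 0.792 for epidermis (0.652 to 0.940, adjusted p = 0.0820), 0.882 for neurons (0.688 to 1.08), 0.980 for skeletal and cardiac muscle (0.827 to 1.13), 0.981 for pancreas (0.815 to 1.16), 1.02 for germ cells (0.804 to 1.24) and 1.08 for photoreceptors and lens (0.895 to 1.27). Of the members with the most distal peaks in each list, the insulin gene INS had 33, PRSS1 18 and CTRB1 22 in the pancreas list, and GDF9 had 32, PIWIL1 28 and PRM1 25 among germ cell genes. PDE6B had 26 and ABCA4 23.5 in the photoreceptor list. MYL3 (29), MYOD1 (21) and RYR1 (21) led the muscle list, RBFOX3 (24.5), SLC17A7 (23.5) and CAMK2A (22.5) the neuron list, and TGM3 (25), IVL (17) and CDSN (16.5) the epidermis list. The epidermis list passed the test with 25 kb windows (0.704-fold, adjusted p = 0.0254) and with covered bases (0.743-fold, adjusted p = 0.0405).

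**Figure D3:**
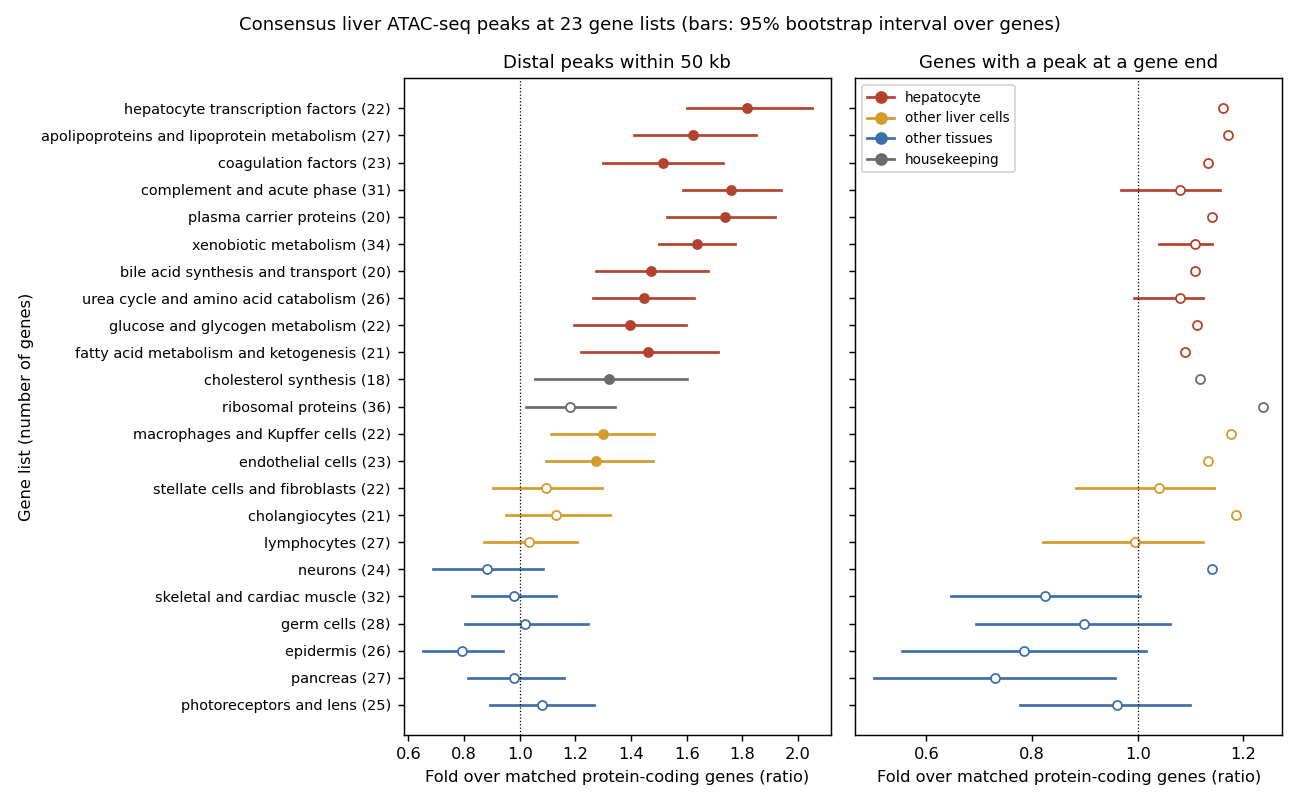
Fold over matched protein-coding genes (ratio, x axes) in distal peaks within 50 kb (left) and in the share of genes with a peak at a gene end (right) for 23 gene lists (y axis, number of genes in brackets), coloured by class, with bars for the 95% bootstrap interval over genes and filled points for adjusted p under 0.05. The 10 hepatocyte lists lie between 1.40 and 1.82 on the left; on the right no point is filled, and lists in which every gene has such a peak have no visible bar because resampling genes cannot vary them.

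Each class also differed from its matched genes in the share with an accessible end; differences between classes were not tested for this share. All but 4 of the hepatocyte genes had an accessible end (98.4% against 88.1% of matched genes, 1.12-fold, 95% interval 1.10 to 1.13, adjusted p = 4e-05), as did all 54 housekeeping genes (83.7% of matched genes, adjusted p = 0.00191) and all but 6 genes of the other liver cells (94.8% against 86.1%, 1.10-fold, 1.05 to 1.14, adjusted p = 0.00804). Genes of other tissues lay below their matched genes, with 39 of 162 lacking an accessible end (75.9% accessible against 85.7%, 0.886-fold, 95% interval 0.807 to 0.965, adjusted p = 0.00094). The 4 hepatocyte genes without an accessible end were C4A and C4B, neighbouring complement genes that are near-identical copies, FMO5, a monooxygenase gene, and CBS, which encodes cystathionine beta-synthase. Of 13 other genes with near-identical copies, chosen after the values of these 4 had been seen, 2 had an accessible end. Among the other-tissue genes, the 120 without a copy of the same name stem within 100 kb did not pass (0.949-fold, 0.863 to 1.03, p = 0.162), and the 42 with such a copy stood at 0.695-fold (0.522 to 0.869), in a split made after the data were seen. Those 120 genes were low with 500 bp either side (0.800-fold, p = 2e-05) and with peaks of at least 300 bp (0.835-fold, p = 0.00011). The call for the other liver cells was lost with peaks of at least 300 bp (1.07-fold, adjusted p = 0.104).

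By list, the shares were lowest for pancreas (16 of 27 genes), epidermis (17 of 26) and skeletal and cardiac muscle (23 of 32), with adjusted p = 0.0666, 0.110 and 0.101. None of the 23 lists passed the threshold; ribosomal protein genes, all 36 of them accessible, also had adjusted p = 0.0666. The muscle myosin genes MYH1, MYH2 and MYH3, the epidermal genes KRT1, FLG and FLG2, and the pancreatic genes GCG, CELA2A and CELA2B had no accessible end. Neither did the germ cell genes DDX4, TNP1 and TNP2 (22 of 28 accessible in the list) or the photoreceptor genes GNAT1, PDE6B and CRX (21 of 25). All 24 neuron genes had an accessible end (adjusted p = 0.207). Among the other liver cells, LRAT and THY1 were without one in the stellate list (20 of 22) and CD8B, KLRB1 and KLRD1 in the lymphocyte list (23 of 27), while the macrophage, endothelial and cholangiocyte lists were complete. With 500 bp in place of 1 kb either side, muscle (0.598-fold, adjusted p = 0.00023), epidermis (0.630-fold, adjusted p = 0.00713) and pancreas (0.674-fold, adjusted p = 0.0167) passed, as did ribosomal protein genes (1.30-fold, adjusted p = 0.00981). With peaks of at least 300 bp, photoreceptors and lens passed as well (0.672-fold, adjusted p = 0.00839). The neuron list turned from 1.14-fold to 0.941-fold with 500 bp and to 0.996-fold with peaks of at least 300 bp, without passing in any setting.

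Ranked over all 19974 protein-coding genes, those with the most distal peaks included RXRA (44), FGL1, NNMT and SPSB1 (43.5 each), ELL2 (43), ZBTB16 (41.5), APMAP and PWWP2B (41 each), and BRSK2 and COL18A1 (40.5 each). LOC110384692, MRPL50 and PXDN followed with 40, then ACSL1, C8B, CFAP46, CROCC2 and SDC1 with 39.5, and APOB with 39. Across the genome the median was 13.5 (quartiles 8 and 19), and 1.43% of genes had no distal peak. Of the genes named here RXRA, ACSL1, C8B and APOB belonged to a list, in each case a hepatocyte list. FGL1 encodes a secreted protein made by hepatocytes and NNMT a nicotinamide methyltransferase abundant in liver. MRPL50, a mitochondrial ribosomal protein gene at 101387633 to 101398618 on chromosome 9, neighbours BAAT, and NNMT neighbours ZBTB16 on chromosome 11, so a high count can belong to a neighbour's surroundings.

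The RXRA region shows such a stretch. RXRA spans 134326455 to 134440585 on chromosome 9, both of its ends were accessible, and 60 peaks had their midpoint inside the gene. With 50 kb added on either side the region held 97 peaks in 214.1 kb, or 45.3 per 100 kb. CTRC, a pancreatic protease gene at 15438443 to 15449242 on chromosome 1, stood at the median of the other-tissue genes with 13 distal peaks. Its region held 18 peaks in 110.8 kb, or 16.2 per 100 kb; 1 end of CTRC was accessible, and the neighbouring elastase genes CELA2A and CELA2B had no accessible end.

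**Figure D4:**
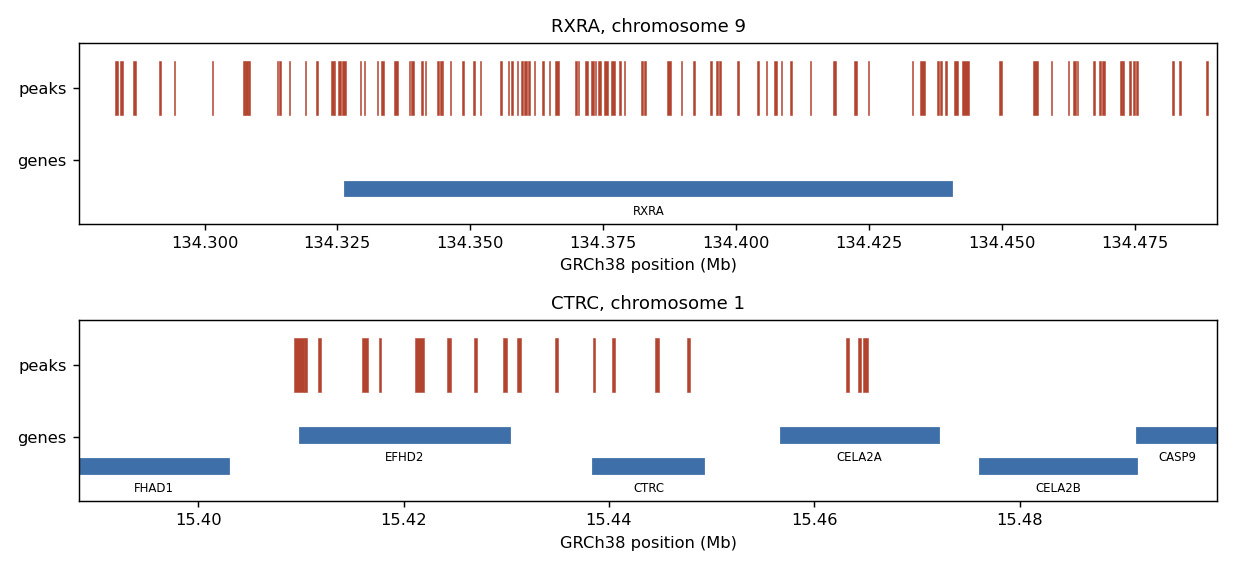
Consensus peaks (red) and protein-coding genes (blue, names below) drawn to scale along GRCh38 position in Mb (x axes) for RXRA with 50 kb on either side (top) and CTRC with 50 kb on either side (bottom). The RXRA region holds 97 peaks in 214.1 kb and the CTRC region 18 in 110.8 kb; the x axes cover different lengths.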

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

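The choice of the end with more or fewer peaks, the keeping of peak-free stretches and the split of other-tissue genes by neighbouring copies were chosen after the data were seen; the other alternatives were set before. The location of peaks, the excess width at gene ends, the correlation with gene density and both differences between classes kept their direction and their side of the threshold under each alternative run for them. So did the results on distal peaks for the 10 hepatocyte lists and for the 4 classes. Motif tests, repeat content, CpG classes, any transcript start and the removal of secondary peaks were not run. With no depth or donor values, sites missed by the consensus cannot be counted.

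With peaks of at least 300 bp, 221682 peaks remained. Shares of protein-coding, long non-coding RNA and pseudogenes with an accessible end were then 83.7%, 54.3% and 24.8%; with 500 bp either side they were 84.2%, 54.3% and 26.4%, and with an overlap of at least 100 bp 87.1%, 62.8% and 32.3%. These follow from fewer peaks, narrower windows and a stricter overlap.

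For accessible ends with peaks of at least 300 bp, the call for other liver cells was lost (1.07-fold). Apolipoproteins (1.23-fold), ribosomal proteins (1.31), muscle (0.788), epidermis (0.685), pancreas (0.680) and photoreceptors and lens (0.672) passed the threshold, while stellate cells (0.931) and neurons (0.996) turned below 1 without passing. With 500 bp either side, ribosomal proteins (1.30), muscle (0.598), epidermis (0.630) and pancreas (0.674) passed, and lymphocytes (1.04) and neurons (0.941) changed sides of 1 without passing. Other-tissue genes without a neighbouring copy passed with 500 bp (0.800) and with peaks of at least 300 bp (0.835).

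For distal peaks, the macrophage call was lost with peaks of at least 300 bp (1.21), 100 kb windows (1.18) and covered bases (1.24), and the cholesterol synthesis call with 100 kb windows (1.23). Ribosomal proteins passed with 100 kb windows (1.24), and epidermis with 25 kb windows (0.704) and covered bases (0.743). Lists that did not pass in any setting changed sides of 1: lymphocytes with peaks of at least 300 bp (0.934), 100 kb windows (0.979) and covered bases (0.965); muscle with peaks of at least 300 bp (1.03), 25 kb windows (1.02) and 1 gene per 250 kb (1.01); germ cells with peaks of at least 300 bp (0.991), 25 kb windows (0.891), 1 gene per 250 kb (0.943) and covered bases (0.985); and pancreas with 1 gene per 250 kb (1.01). The cause of these changes was not tested. Of 84 genes named for their distal peaks, 73 lay above the 90th percentile, and 90.6% of their alternative values did too. These genes were picked for high counts, and the alternatives recount largely the same peaks, so neither share is independent support.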

Other observations

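The gene families below, the ring test, the test at the end with fewer peaks, the use of ribosomal protein genes against high transcription and the tests on gene copies were chosen after the data were seen; the test with 1 gene per 250 kb was set before.

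Several gene families had fewer accessible ends than matched genes. Of the olfactory receptor genes 84 had an accessible end (21.4% of them, Wilson 95% interval 17.7 to 25.8), as had 5 of 25 bitter taste receptor genes (20.0%, 8.86 to 39.1), 6 of 39 beta-defensin genes (15.4%, 7.25 to 29.7), 16 of 35 MAGE genes (45.7%, 30.5 to 61.8) and 43 of 94 keratin-associated protein genes (45.7%, 36.04 to 55.8). Clustered protocadherin genes (60.4%, 46.9 to 72.4) and interleukin and interferon genes (72.5%, 62.6 to 80.6) were low too. Adjusted p for these 7 families ran from 4e-05 to 0.00992, over 16 families tested. Olfactory receptor genes also had few distal peaks (0.417-fold, 0.389 to 0.447), a smaller deficit than that of their ends (0.273-fold, 0.221 to 0.325). Zinc finger genes of the ZNF series, many of which also lie in tandem clusters, had accessible ends in 92.5% of 517 genes (89.8 to 94.4) while their distal peaks stood at 0.550-fold (0.509 to 0.592). Distal peaks were also few around MAGE (0.390-fold), beta-defensin (0.393-fold), bitter taste receptor (0.495-fold), keratin-associated protein (0.579-fold) and clustered protocadherin genes (0.694-fold), and around histone genes (0.666-fold, with an accessible end in 85.9%), with adjusted p from 1.78e-05 to 8e-05. Matching did not include the chromosome, and the X chromosome held 55.1 peaks per Mb against 126.2 over all chromosomes used. A family with many members on X, as may hold for MAGE genes, can be low for that reason, which was not tested.

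Distal peaks were more numerous than around matched genes for HOX genes (1.40-fold, 1.31 to 1.48, 38 of 40 with an accessible end), UDP glucuronosyltransferase genes (1.36-fold, 1.14 to 1.57), cytochrome P450 genes (1.248-fold, 1.11 to 1.38), collagen genes (1.20-fold, 1.02 to 1.40), interleukin and interferon genes (1.14-fold, 1.05 to 1.23), whose ends were low, and solute carrier genes (1.13-fold, 1.08 to 1.19), with adjusted p from 1.78e-05 to 0.0231; some of the glucuronosyltransferase and cytochrome genes also belong to the hepatocyte lists. In all families tested, members that lie side by side share peaks but were counted as separate genes. Intervals are too narrow and p-values too small to that extent, above all for clustered families such as HOX and protocadherin genes. No value with 1 gene per 250 kb is given for the families. All 40 proteasome subunit genes and 75 of 77 mitochondrial ribosomal protein genes had an accessible end, with distal peaks at 0.897-fold (0.769 to 1.03) and 1.02-fold (0.907 to 1.14). Of all 100 kb windows the richest held 58 peaks, on chromosome 9 from 134300001 to 134400000, and overlapped RXRA. ARHGEF10L (52 peaks), MBNL2 and EXT1 (51 each), EPAS1 (48) and the cholesterol exporter gene ABCA1 (48) overlapped others near the head of the ranking.

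The excess of distal peaks around hepatocyte genes, 1.59-fold within 50 kb, may mark regulatory sites of liver-expressed genes. In the ring from 100 to 500 kb the excess was 1.08-fold (1.04 to 1.12). Regional accessibility or base composition that extends over that distance thus accounts for a small part at most. The ring cannot decide on regional effects that stay within 100 kb. With 1 gene per 250 kb it stayed at 1.58-fold (1.51 to 1.65), which counts against gene clusters entering several times. The value at the end with fewer peaks, 1.64-fold (1.57 to 1.71), decides nothing on a misplaced window, because that end is picked by its own peaks and a misplaced window would dilute an excess. Ribosomal protein genes, highly transcribed in most cells, stood at 1.18-fold (1.02 to 1.34) within 50 kb, below the hepatocyte interval (1.53 to 1.66). Within that window this counts against a high rate of transcription as the whole cause. With 100 kb windows ribosomal protein genes passed the threshold, and the comparison with the hepatocyte interval is given for 50 kb only. Base composition within 100 kb, down to the scale of single peaks, stays open, since no sequence was used here. Apart from the rate of transcription, no biological explanation was tested, because the design has 1 group.

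The low share of other-tissue genes with an accessible end could come from reads shared between neighbouring copies, which would remove peaks. The 120 genes without a copy of the same name stem within 100 kb stood at 0.949-fold (0.863 to 1.03, p = 0.162), so the bound set in advance against this explanation was not met, and the 42 genes with a copy stood at 0.695-fold (0.522 to 0.869). Their shares, 82.5% without and 57.1% with a copy, differed when labels were permuted (p = 0.00212). Genes with a copy can be neighbours of each other and are then not independent, so this p-value is too small to that extent. With 500 bp either side, a setting looked at only after that result, genes without a copy were low too (0.800-fold, 0.700 to 0.900), which shared reads between such copies would not give. All 47 hepatocyte genes to which the name rule gives a copy had an accessible end. With 500 bp either side 97.9% of them did, and with peaks of at least 300 bp 93.6%. A copy by this rule therefore does not by itself empty gene ends. The rule does not measure how alike the sequences are, and it misses C4A and C4B, which had no accessible end. Shared reads stay open for the 42 genes, and no biological explanation was tested.

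The hepatocyte genes C4A, C4B, FMO5 and CBS had no accessible end, and reads that match a near-identical copy equally well are a candidate explanation. Of 13 other genes with near-identical copies 2 had an accessible end (15.4%, Wilson 95% interval 4.33 to 42.2), compared with 84.4% of matched genes, but the 13 lie in a few duplicated regions of chromosomes 5, 16 and 21 and are not independent. C4A and C4B each had 2 peaks inside the gene, FMO5 10 and CBS 1. Among the copies U2AF1 had 2 and the other 12 had none. Several copies are short, such as BOLA2B at 30192932 to 30193666 on chromosome 16. Distal peaks numbered 19 at C4A, 27 at C4B, 19 at FMO5 and 10 at CBS, compared with 0 to 6.5 at the copies. Gene length was not matched and the reach of the duplicated stretches was not measured, so neither count decides on shared reads. Shared reads stay open for these 4 genes, and whether FMO5 and CBS share sequence with another locus was not tested. CBS, at 43053191 to 43076873 on chromosome 21, lies near U2AF1, at 43092956 to 43107578, so CBS and that copy are not independent. No biological explanation was tested.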
